A study of Mus musculus with 3 samples.

How the data were processed

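Gene expression was measured in single cells from 3 mouse pancreatic tumours grown under the skin. The mice had received chidamide, an inhibitor of histone deacetylases, at 0, 12.5 or 25 mg/mL per the labels, and 1 tumour was taken per group. Tissue was digested to single cells, red cells were lysed where needed, and libraries were made from polyA RNA on the 10x Genomics platform. The submitters named Cell Ranger (version not given) and Seurat 4.0.0 as tools, with the builds mm10 and GRCh38; the deposited matrices held mouse genes only.

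The deposited values were counts: whole numbers of UMIs, the distinct molecules seen per gene and cell, without normalisation. Each matrix listed 32285 features and only barcodes that the authors had taken as cells. Depth was 88713481 UMIs in 7936 barcodes at 0, 86187729 UMIs in 7282 barcodes at 12.5, and 79381566 UMIs in 6844 barcodes at 25. Median UMIs per barcode were 6695.5, 8720 and 10115, and median genes 2228.5, 2841.5 and 3144.

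Cells needed at least 200 genes, at least 500 UMIs and under 20% mitochondrial UMIs, which removed 10 barcodes. Scrublet, in scanpy 1.11.5 with an expected doublet rate of 6%, called 206 doublets in the 0 library (2.6%) and 0% in both treated libraries. A rate of 0% in libraries of this size means that the caller did not work there, so the treated libraries still hold doublets. The 21846 retained cells, 7729, 7275 and 6842 by dose, were clustered together without batch integration. Counts were scaled to 10000 UMIs per cell and log-transformed, and 3000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1.0 were used (igraph 0.11.9, leidenalg 0.10.2, anndata 0.12.19, scikit-learn 1.9.0).

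Clusters were named from marker genes fixed before the data were examined, as were the gene lists, the values to be compared, the rule for named genes and most alternatives. The rule that turns markers into names was set after the clusters had been seen, and the rule used was the third one tried. A cluster needed at least 3 markers of a class in at least 20% of its cells at 2-fold or more over the other clusters, and a mean log2 fold of the class's markers of at least 1. With several such classes the one with the most markers gave the name; under the second rule, which chose by score, cluster 1 with 165, 203 and 106 cells was not phagocyte-like. Clusters left without a name were then set against the named ones for at least 3 tumour epithelial markers. Clusters with at least 3 markers of a further lineage, at 4-fold or more over the median cluster of their class, stayed unnamed. So did clusters with UMIs under one part in 3 of their library's median and no class marker among their 10 leading genes. Clusters high in Krt8 and Krt18 that met the tumour epithelial rule are given by number. In clusters 2, 3 and 22, markers of another class outnumbered their own among the leading 10 genes. That class was keratinocyte-like in clusters 2 and 3 and fibroblast-like in cluster 22. Names end in "-like" because no sorted or annotated cells were available.

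Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. For each class with at least 50 cells per library, UMIs were summed per library and scaled to the same total in every class and library (CPM). Ratios of CPM carry exact 95% intervals for a ratio of 2 Poisson counts. Intervals of list medians came from 1000 Poisson draws. All intervals cover counting error only: with 1 library per group the spread between animals is unknown, so no test was run and no p-value is given. Where a library had no UMI of a gene, folds were set against a floor of 3 UMIs.

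For each of 33 fixed gene lists, the median log2 ratio over members with at least 20 UMIs in the class was taken where at least 5 members were measured. Its percentile among 10000 random lists of the same size, matched within 100 genes of rank on expression, describes where the median lay among other genes. Medians were taken in 4 classes and for 3 pairs of libraries. Lists are printed where the median lay outside the central 95% of random lists on one side at both doses, and for a few further lists; this choice, and that of the 4 lists discussed first in each class, was made after the data were seen. Both doses were set against the same 0 library, so likeness between the doses is no repeat of a result. In all, 12 list or marker genes matched no feature, and 78 symbols occurred more than once.

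Named genes had at least 50 CPM in at least 1 of the libraries and were not mitochondrial, ribosomal, antigen-receptor or predicted genes, nor Xist, Tsix or the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Genes over 10 times higher in another class in every library were left out. The rest were ranked by the bound nearest 0 of the interval of the 25 to 0 ratio, kept if the 12.5 to 0 ratio had the same sign, and the first 10 higher and 10 lower were taken per class. Some genes of other cells pass this rule, because they were not 10 times higher elsewhere in every library. Members of the fixed lists are named in addition.

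Gene positions came from GENCODE M21 on GRCm38, the assembly also called mm10; 99.6% of feature IDs had a position. Medians by chromosome and by windows of 40 neighbouring genes used genes above 10 CPM, with 100 shuffles of gene order for comparison. A score per cell, the ratio of UMIs on chromosomes 1, 5, 11 and 15 to UMIs on 2 and 3, used cells with at least 2000 UMIs; those chromosomes were chosen after the medians were seen.

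The interval and list steps were tested on simulated data drawn from the phagocyte-like sums. With 200 of 12452 genes set to a log2 change of 1, the intervals covered the truth in 96.0% of genes and all 200 changed genes lay on the right side. Counts were drawn as Poisson, which the intervals assume, and changed genes had at least 50 CPM, so this result checks the calculation only. The simulation held no spread between cells or animals. Of 200 random lists, 9 fell outside the central 95%, and a planted list reached percentile 100 with a median of 0.97.

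Alternatives for cells were a stricter filter (500 genes, 1000 UMIs, 10% mitochondrial), no mitochondrial limit, doublets kept, Leiden resolutions 0.5 and 2.0, each library clustered alone, a class per cell from marker scores, and cells thinned to 1000 UMIs. Alternatives for expression were scaling by the median of ratios, the mean of cell CPM, other UMI minimums, doublets kept, the stricter filter, and the same mix of clusters in every library. The same mix used only clusters with at least 20 cells in each library. Chosen after seeing the data were the removal of the top 6% of Scrublet scores in every library, cluster 13 alone, ratios less those of neighbouring genes, lists without genes over 10 times higher in another class, tumour clusters without the low-UMI cluster 5, phagocyte sub-clustering at resolution 2.0, and clustering without 667 genes (list members and leading genes). Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.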

Results

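Single-cell RNA was counted in 3 mouse pancreatic tumours grown under the skin, 1 from each chidamide group. Chidamide inhibits histone deacetylases, the enzymes that take acetyl groups off histones. The labels give its level as 0, 12.5 and 25 mg/mL, and the groups are called the 0, 12.5 and 25 libraries here. The titles of both treated libraries carry the name pan02, a mouse pancreatic cancer line, and that of the 0 library does not; the labels do not say which line any tumour grew from. There were no replicates in any group, so each value stands for 1 tumour and its interval covers counting error alone. After filtering, 7729, 7275 and 6842 cells remained. Of these cells, 5.98%, 15.2% and 9.84% fell in clusters that could not be named.

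The design asks how the immune cells of the tumour differ with chidamide. Neutrophil-like cells, the short-lived granulocytes that express S100a8 and S100a9, made up far more of the named immune cells in the treated tumours. Their share was 19.7% [18.3, 21.1] at 0, 49.1% [47.0, 51.2] at 12.5 and 64.4% [62.4, 66.4] at 25. That was 2.5-fold higher at 12.5 and 3.28-fold higher at 25 than at 0. Phagocyte-like cells, the macrophages, monocytes and dendritic cells led by Apoe and C1qa, made up less. Their share was 70.3% [68.7, 71.9], 43.9% [41.8, 46.0] and 32.4% [30.5, 34.4]. T cell-like cells were 10.0% [9.03, 11.1], 7.07% [6.04, 8.21] and 3.18% [2.48, 4.0] of the named immune cells, 1.42-fold lower at 12.5 and 3.16-fold lower at 25.

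**Figure D1:**
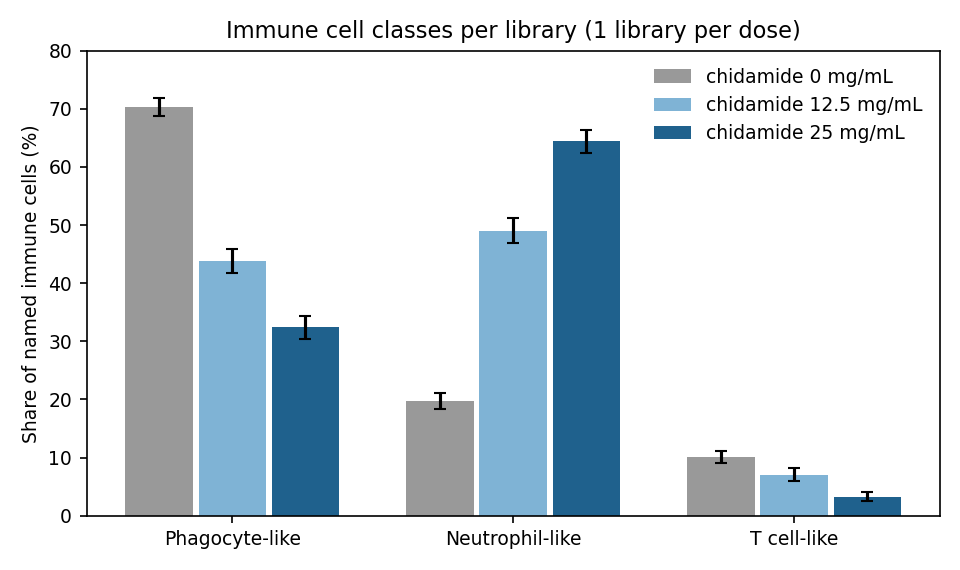
Share of named immune cells (percent, vertical axis) in each of 3 classes, 1 bar per library and dose, with exact 95% binomial intervals. Neutrophil-like cells stood at 19.7%, 49.1% and 64.4%, and phagocyte-like cells at 70.3%, 43.9% and 32.4%.

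The counts behind these shares were 638, 1097 and 1399 neutrophil-like, 2282, 981 and 704 phagocyte-like and 326, 158 and 69 T cell-like cells, among 3246, 2236 and 2172 named immune cells. As log2 ratios to the 0 library, the neutrophil-like share was 1.32 [1.18, 1.46] at 12.5 and 1.71 [1.58, 1.85] at 25. The phagocyte-like share was −0.68 [−0.79, −0.57] and −1.12 [−1.24, −0.99], and the T cell-like share −0.51 [−0.79, −0.23] and −1.66 [−2.06, −1.28]. Between the treated libraries, 25 against 12.5, the ratios were 0.39 for neutrophil-like, −0.44 for phagocyte-like and −1.15 for T cell-like cells. Among all cells rather than immune cells, neutrophil-like cells were 8.26%, 15.1% and 20.4%, phagocyte-like cells 29.5%, 13.5% and 10.3%, and T cell-like cells 4.22%, 2.17% and 1.01%. Named immune cells together made up 42.0%, 30.7% and 31.8% of all cells. Neutrophil-like cells held few UMIs, a median of 1273.5, 1087 and 990, so their number depends on the lower limit on UMIs per barcode.

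Stromal cells were few. Fibroblast-like cells, led by matrix genes such as Col3a1 and Sfrp1, numbered 20, 96 and 94, or 0.259%, 1.32% and 1.37% of all cells. Endothelial-like cells numbered 30, 20 and 27, and pericyte-like cells 17, 11 and 6. The log2 ratio of the fibroblast-like share was 2.35 [1.64, 3.12] at 12.5 and 2.41 [1.70, 3.18] at 25, and it was 1.54 and 1.46 when list members and leading genes were kept out of the clustering.

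Within the T cell-like and NK-like cells, those with CD8 T cell markers, the cells that kill tumour cells by contact, made up less of the treated libraries. They were 171 cells or 52.5% at 0, 44 cells or 27.9% at 12.5 and 16 cells or 23.2% at 25. The log2 ratio was −0.91 [−1.43, −0.43] at 12.5 and −1.18 [−2.02, −0.44] at 25. Gamma-delta T-like cells, with Il17a and Trdc, numbered 9, 15 and 9, a log2 ratio of 1.78 [0.50, 3.16] and 2.24 [0.73, 3.75] of their share. NK-like cells numbered 17, 17 and 3, with intervals that include 0 at both doses: 1.04 [−0.01, 2.10] and −0.26 [−2.68, 1.53]. Unnamed sub-clusters held 129, 82 and 41 of these cells. Of them, 48, 51 and 19 lay in a sub-cluster led by Ly6c2, which had under 3 detected markers of any subset. Slamf6 and Tcf7, genes of less differentiated T cells, were also among its 10 leading genes.

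Within the phagocyte-like cells, macrophage-like cells were 90.0% at 0, 70.3% at 12.5 and 77.8% at 25. Monocyte-like cells, the blood-derived precursors marked by Ly6c2 and Ccr2, were 2.94%, 14.8% and 10.1%, from 67, 145 and 71 cells. Their log2 ratio was 2.33 [1.90, 2.77] at 12.5 and 1.78 [1.28, 2.28] at 25. cDC1-like cells, the dendritic cells with Xcr1 and Clec9a that present antigen to CD8 T cells, numbered 46, 8 and 1, a log2 ratio of −1.31 [−2.60, −0.21] and −3.83 [−9.16, −1.28]. cDC2-like cells numbered 22, 38 and 21, a log2 ratio of 2.01 [1.21, 2.83] and 1.63 [0.69, 2.56]. The remaining 80, 90 and 56 phagocyte-like cells could not be named.

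Phagocyte-like cells of the treated libraries held less RNA of MHC class II presentation, the genes that show antigen to CD4 T cells. The median log2 ratio over all 13 genes of the list was −0.58 [−0.96, −0.52] at 12.5 and −0.82 [−1.0, −0.63] at 25, at percentile 0 of the 10000 random lists in each case. H2-Ab1, a class II chain, was at 4793, 2472 and 2184 CPM by dose. Cd74, the chain that guides class II to its compartment, was at 6006, 2822 and 3023 CPM. Ciita, the factor that switches these genes on, had log2 ratios of −1.34 [−1.73, −0.96] and −1.54 [−2.06, −1.05]. Ifi30, a thiol reductase of the same list, was at 646, 740 and 662 CPM. H2-Aa and H2-Ab1 also lead phagocyte clusters 0 and 1, and H2-Eb1 and Cd74 cluster 1; with these and all list genes kept out of the clustering, the medians were −0.56 and −0.73. In macrophage-like sub-clusters alone the medians were −0.92 and −0.83.

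The interferon gamma response was lower too, with medians of −0.34 [−0.40, −0.20] at 12.5 and −0.54 [−0.65, −0.46] at 25 over 22 measured genes, again at percentile 0; with the same mix of clusters the median at 12.5 was −0.18. Iigp1, a GTPase that acts against parasites inside cells (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634), was at 130, 57.1 and 31.3 CPM, log2 ratios of −1.19 [−1.35, −1.02] and −2.05 [−2.32, −1.79]. Cxcl9, which draws T cells, was at 341, 201 and 229 CPM. Cd274, the checkpoint ligand PD-L1, was at 89.8, 123 and 78.0 CPM. MHC class I presentation had medians of −0.10 and −0.28, at percentiles 2.7 and 0 of random lists. The type I interferon response stood at 0.01 and −0.08, percentiles 35.7 and 1.8.

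Hypoxia and glycolysis genes were higher in the phagocyte-like cells, with medians of 0.42 [0.37, 0.48] and 0.39 [0.34, 0.42] over 26 genes, at percentile 100 of random lists. Vegfa, the growth factor of blood vessels, was at 100, 201 and 171 CPM, and Ldha, which makes lactate, at 430, 591 and 560 CPM. P4ha1, of the same list, had log2 ratios of −0.25 and −0.29. Oxidative phosphorylation had medians of 0.27 and 0.18 (0.08 and 0.09 with doublets kept), proliferation 0.16 and 0.23 (−0.35 at both doses with the same mix of clusters in every library), and dissociation and immediate early genes −0.19 and −0.12. Complement and lipid macrophage genes stood at −0.27 and −0.05, percentiles 0 and 19.1, and at −0.02 and 0.03 in macrophage-like sub-clusters alone. Arg1, the arginine-splitting enzyme of alternatively activated macrophages, was at 253, 785 and 498 CPM, while its list had medians of 0.09 and 0.08. Lists of extracellular matrix (1.47, 0.86) and epithelial state (1.14, 1.10) were higher as well, but most of their measured members belong to tumour cells or fibroblasts: Krt18 was at 47.4, 113 and 110 CPM here against 906, 1740 and 2150 CPM in the tumour clusters without cluster 5.

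By the rule for single genes, 10 higher and 10 lower genes were named in the phagocyte-like cells. Ctsk, the collagen-cutting protease of osteoclasts (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362), led the higher genes at 5.35, 815 and 372 CPM. Mmp9, Acp5 and Atp6v0d2, also known from osteoclasts, were at 1.78, 291 and 103, at 71.8, 593 and 379, and at 4.71, 72.7 and 37.0 CPM. A sub-cluster of 1, 50 and 17 cells held 89.3%, 91.5% and 99.3% of the Ctsk UMIs of this class. The other higher genes were Ifitm1, AA467197, Mmp12, Nt5e, Ptgs1 and S100a4, with log2 ratios at 25 between 1.38 for S100a4 and 2.85 for Ifitm1. Lower genes outside the lists were Naaa at 147, 45.0 and 42.5 CPM, C4b and Clec12a. Ccl8, a chemokine of the list of myeloid-attracting factors, was at 1132, 599 and 487 CPM. Acod1, which makes itaconate, was at 257, 171 and 75.3 CPM, against 2394, 2489 and 2474 CPM in neutrophil-like cells. Ctsk and Acp5 lead cluster 12, Ifitm1 leads the cDC2-like cells and Naaa is a cDC1 marker, and the shares of those cells in the class differed in the same direction as these 4 genes.

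Neutrophil-like cells of the treated libraries held less interferon-induced RNA. The type I interferon response had medians of −0.75 [−0.96, −0.65] at 12.5 and −1.11 [−1.35, −0.96] at 25 over 25 of 30 genes, at percentile 0 of random lists. Rsad2, the antiviral enzyme viperin (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), was at 1096, 654 and 390 CPM. Isg15, a ubiquitin-like protein that interferon induces, was at 938, 634 and 615 CPM, and Ifit3 at 309, 123 and 88.4 CPM. The interferon gamma response stood at −0.56 [−0.81, −0.31] and −1.0 [−1.24, −0.71] over 19 genes, and at −0.24 at 12.5 over genes with at least 100 UMIs. Cxcl10, a T cell-attracting chemokine, was at 1270, 380 and 389 CPM.

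MHC class I presentation in these cells had medians of −0.40 [−0.46, −0.23] and −0.69 [−0.76, −0.51] over 22 genes. H2-K1 was at 1138, 838 and 725 CPM, and B2m, the light chain of class I, at 1129, 859 and 663 CPM. Cd274 was at 922, 887 and 856 CPM. Granule and maturation genes stood at −0.21 [−0.53, −0.13] and −0.57 [−0.68, −0.26] over 16 genes, with S100a8 at 9697, 8862 and 6922 CPM and the antibacterial granule protein Ltf at 67.2, 122 and 134 CPM. The list of myeloid-attracting factors (−0.85, −0.47) held members that went both ways: Cxcl2, which draws neutrophils, was at 16180, 18350 and 27080 CPM, and Ccl2, which draws monocytes, at 208, 85.0 and 91.1 CPM. The inflammatory fibroblast list (−0.90, −0.81), MHC class II (−1.04, −0.95), oxidative phosphorylation (0.23, 0.16) and epithelial state (0.60, 0.77) also lay outside the random lists at both doses. Over the alternatives, granule and maturation genes at 25 lay between −0.58 and −0.33 and the inflammatory fibroblast list at 25 between −0.82 and −0.40. Epithelial state at 12.5 lay between 0.15 and 0.66. All 8 measured class II genes were over 10 times higher in another class, and Krt18, a tumour keratin, was at 183, 334 and 385 CPM in neutrophil-like cells.

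Higher single genes in the neutrophil-like cells were Thbs1, a matrix protein, at 336, 566 and 1046 CPM, the cytokine gene Il1a at 323, 380 and 760 CPM, and Cxcl3 at 200, 252 and 495 CPM. Eml1, Mpp7, Tex14 and Enpp2 were also higher, with log2 ratios at 25 of 1.88, 1.21, 1.70 and 1.37. Rhox5 and Dcn, tumour genes of the treated libraries, passed the rule at 69.0 and 156 CPM in the 12.5 library, and the tumour gene Lgals7 was lower. The remaining lower genes were all induced by interferon, among them Ifit2 at 180, 36.9 and 35.1 CPM and Gbp5 at 210, 105 and 47.2 CPM. Acod1 leads a neutrophil cluster; with such genes and all list genes kept out of the clustering, the type I interferon medians were −0.76 and −1.12.

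T cell-like cells of the treated libraries held more RNA of naive and memory T cell genes and less of inhibitory receptors. The naive and memory list had medians of 0.69 [0.45, 0.93] at 12.5 and 0.82 [0.47, 1.28] at 25 over 11 of 12 genes, at percentile 100 of random lists; with doublets kept the median at 25 was 0.35. Il7r, the receptor of a survival cytokine, was at 127, 227 and 397 CPM, and Klf2, a factor of resting T cells, at 906, 1302 and 1452 CPM. Cd27, of the same list, was at 153, 67.4 and 75.3 CPM. Inhibitory receptors and exhaustion stood at −0.61 [−1.0, −0.46] and −0.52 [−0.94, −0.22] over 13 of 16 genes. Pdcd1, which encodes PD-1, was at 329, 164 and 185 CPM, Lag3 at 118, 76.3 and 34.2 CPM, and Ctla4 had log2 ratios of −0.24 and 0.16. The mix of the class differed too: 52.5%, 27.9% and 23.2% of it were CD8 T-like cells. The unnamed sub-cluster led by Ly6c2 held 14.7%, 32.3% and 27.5%. Slamf6 and Tcf7, also among its leading genes, are members of the naive and memory list.

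Cytotoxic effectors had medians of 0.08 [−0.23, 0.21] at 12.5 and −0.96 [−1.24, −0.41] at 25; with no UMI minimum they were −0.45 and −0.42. Perforin, Prf1, which opens pores in target cells, was at 291, 220 and 41.1 CPM, from 250, 98 and 6 UMIs. Of the granzymes, Gzmc was at 4.66, 2645 and 137 CPM and Gzmf at 104, 7669 and 0 CPM, from 89, 3416 and 0 UMIs. The regulatory T programme stood at −0.12 [−0.32, 0.03] and 0.59 [0.05, 0.75], with Il2ra at 54.8, 76.3 and 253 CPM. With doublets kept, the median of this list at 25 was −0.04. A sub-cluster of 44, 16 and 16 cells had 6 regulatory T markers but stayed unnamed for low UMIs. Il1rl1 was among its leading genes, and its share had log2 ratios of −0.41 [−1.34, 0.44] and 0.78 [−0.14, 1.63]. At sub-clustering resolution 2.0, a named regulatory T-like cluster held 24, 12 and 13 cells. The mix of these cells may therefore bear on the list. Scaling by the median of ratios moved all T cell genes by 0.14 at 25 against 0 and by 0.18 at 25 against 12.5, so smaller ratios in this class have no clear sign.

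Further lists in the T cell-like cells also differed. MHC class II (−0.91, −1.97), complement and lipid macrophage (−0.35, −1.08), alternative macrophage (−0.58, −1.14) and myeloid-attracting factors (−1.35, −1.31) were lower, and epithelial state (0.83, 0.97) was higher. With the stricter filter alternative macrophage was 0.47 and −0.67, and MHC class II −1.07 and complement and lipid −0.44 at 25. With doublets kept myeloid-attracting factors were 0.02 at 25. Over all alternatives MHC class II at 25 lay between −3.15 and −0.72. A sub-cluster led by Arg1, Apoe and Trem2 lay inside the T cell-like class with 9, 3 and 0 cells by dose, or 2.76%, 1.9% and 0% of the class. Lgmn, Lyz2, Trem2 and Arg1, among the lower named genes, are phagocyte genes, and Lgmn was at 234, 78.6 and 0 CPM, where 3 UMIs at 25 make 20.5 CPM. Lower genes of other kinds were Prf1, Nrgn, Galnt18, which leads a CD8 T-like sub-cluster, Stk39 and Bend4. Higher named genes were Ifitm1 at 6.99, 285 and 199 CPM, Cd163l1, a gene of gamma-delta T cells, at 15.1, 71.8 and 151 CPM, Gzmc, Il1rl1, Tff1, Socs2, the tumour gene Rhox5, and Hcar2, Ankrd33b and Arg2, which were far higher in neutrophil-like cells. Each of these 10 higher genes had at most 29 UMIs at 25.

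**Figure D2:**
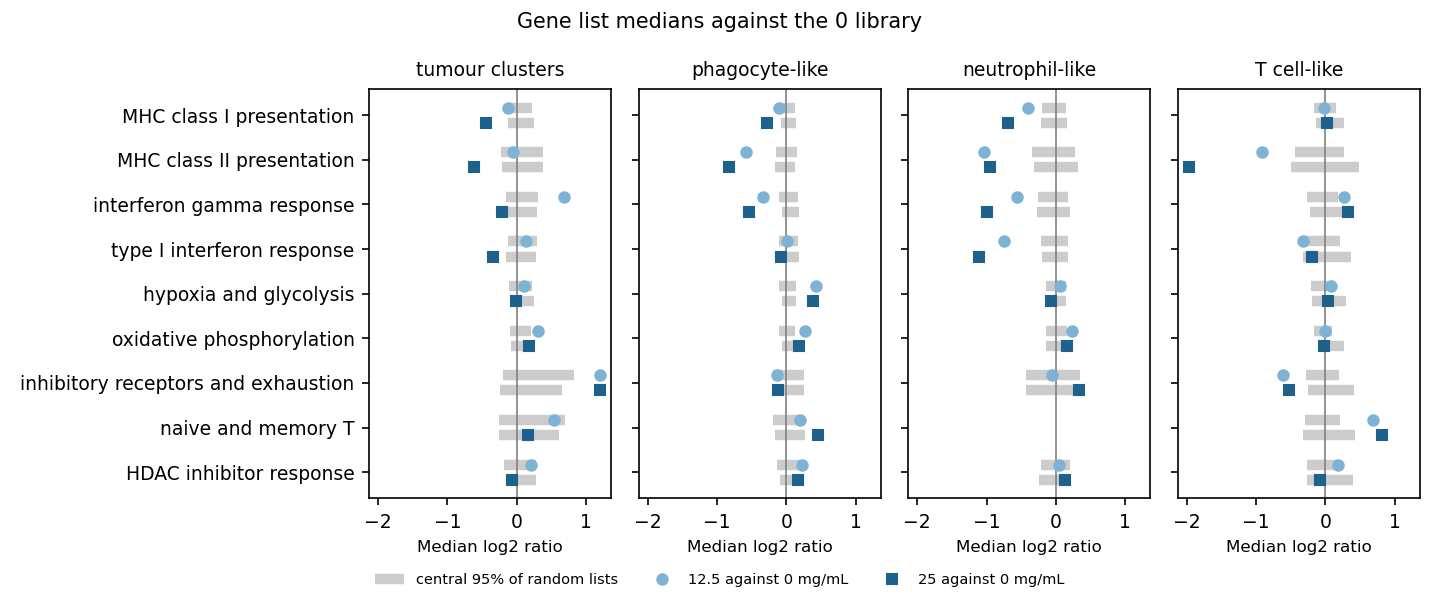
Median log2 ratio against the 0 library (horizontal axis) of 9 gene lists in 4 classes, where enough genes were measured, circles for 12.5 and squares for 25 mg/mL, with grey bars for the central 95% of 10000 random lists. The type I interferon response lay at −0.75 and −1.11 in neutrophil-like cells, and MHC class II at −0.58 and −0.82 in phagocyte-like cells.

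Tumour cells were counted in the Krt8- and Krt18-high clusters 2, 3, 5, 9, 13, 16, 19, 22 and 23, with 3954, 3806 and 3870 cells, or 51.2%, 52.3% and 56.6% of all cells. The libraries lay largely in different clusters. The 0 library lay mainly in clusters 2 (2174 cells), 5 (1103) and 3 (512), the 12.5 library in clusters 22 (813), 19 (748), 16 (633) and 23 (614), and the 25 library in cluster 9 (2189). Only cluster 13, with 115, 318 and 408 cells, and the low-UMI cluster 5 held over 100 cells of each library. A cluster held mostly by 1 library cannot be told from that library, so the sums below compare whole tumours.

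Epithelial genes were higher in the treated tumours, with list medians of 1.43 [0.93, 1.65] at 12.5 and 2.25 [1.94, 2.54] at 25 over 19 of 20 genes. With the same mix of clusters in every library these medians were 0.34 and 0.74, and in cluster 13 alone 0.79 and 3.88. In the tumour the same mix rested on clusters 5, 9, 13 and 16 only. Of the 0 library these held 1103, 25, 115 and 20 cells, while clusters 2 and 3, with 2174 and 512, were left out. Clusters 19, 22 and 23, with 748, 813 and 614 cells at 12.5, were left out too. The keratins Krt18 and Krt19 were at 905, 1738 and 2148 CPM and at 32.2, 99.5 and 127 CPM. Epcam, an adhesion protein of epithelia, was at 0.0756, 0.920 and 9.48 CPM, from 5, 63 and 623 UMIs, of which cluster 13 held 0, 3 and 541, and Cldn7 had log2 ratios of −1.38 and −1.23. Mesenchymal genes stood at 0.36 and 0.46, with the matrix protein gene Fn1 at 1548, 2195 and 2093 CPM and Vim at 3513, 2632 and 3046 CPM.

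MHC class I presentation in the tumour clusters had medians of −0.13 [−0.16, −0.10] and −0.45 [−0.51, −0.39] over 22 genes. Of its members, H2-K1 was at 1156, 582 and 460 CPM, H2-D1 at 1721, 1076 and 911 CPM, and B2m at 879, 517 and 334 CPM. Without cluster 5, tumour genes above 10 CPM on chromosome 17, which holds H2-K1 and H2-D1, had medians of −0.23 and −0.11, and those on chromosome 2, which holds B2m, −0.36 and −0.30. The interferon gamma response differed in direction between the doses, 0.68 [0.54, 0.72] at 12.5 and −0.22 [−0.28, −0.15] at 25, and was −0.86 at 25 against 12.5. In cluster 13 alone those medians were 0.04 and −0.76. Irf1, a factor that interferon gamma induces, was at 122, 215 and 193 CPM. The type I interferon response stood at 0.13 and −0.34, and at −1.15 and −1.76 in cluster 13. MHC class II stood at −0.06 and −0.62, and at 0.53 and 0.15 in cluster 13. Less the median of neighbouring genes on the chromosome, MHC class I was 0.08 at 12.5 and −0.34 at 25.

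Genes fixed as known responses to HDAC inhibitors had tumour medians of 0.21 [0.19, 0.25] at 12.5 and −0.07 [−0.10, 0.00] at 25, percentiles 93.2 and 13.4 of random lists. With the same mix of clusters the median at 12.5 was −0.24, and in cluster 13 that at 25 was 0.35. Cdkn1a, the cell cycle inhibitor p21, was at 89.4, 161 and 154 CPM, and the linker histone gene H1f0 at 112, 148 and 151 CPM. Tubb3, a neuronal tubulin, was at 0.287, 24.9 and 21.4 CPM, while Gsn, which cuts actin filaments, had log2 ratios of −0.48 and −0.07. The same list stood at 0.23 and 0.16 in phagocyte-like, 0.04 and 0.13 in neutrophil-like and 0.18 and −0.08 in T cell-like cells. Proliferation genes had tumour medians of −0.05 and −0.17, and of 0.32 and 0.33 with the same mix of clusters. Over all alternatives these medians lay between −1.07 and 0.32 at 12.5 and between −1.51 and 0.33 at 25. The lists of inhibitory receptors (1.20, 1.20), pro-inflammatory macrophage genes (0.53, 0.71) and complement and lipid genes (−0.41, −0.33) also lay outside the random lists, with many members at low levels: Pdcd1 was at 0.0302, 12.7 and 2.28 CPM. With the same mix of clusters, inhibitory receptors were 0.24 and 0.09 and pro-inflammatory macrophage genes −0.39 and −0.04; without genes over 10 times higher elsewhere, complement and lipid genes were 0.33 and 0.15.

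Among the named tumour genes, Rhox5, an X-linked homeobox gene (ENSMUSG00000095180, chromosome X, 37804842 to 37808876), had 0 UMIs in the tumour clusters at 0. It stood at 322 CPM at 12.5 and 425 CPM at 25. Against a floor of 3 UMIs over the class, that was at least 7102-fold and at least 9381-fold higher. Ptn, a growth factor, was at 0.227, 398 and 128 CPM, and Dcn, a small matrix proteoglycan, at 2.24, 1088 and 267 CPM. Krt7, a duct keratin, was at 0.726, 58.7 and 75.7 CPM. Lum, Cpne8, Cntn5, Col28a1 and Cpq were also among the higher genes. Lgals7, a galectin of squamous epithelia (ENSMUSG00000053522, chromosome 7, 28863853 to 28866284), was at 398, 14.0 and 3.70 CPM, and Tm4sf4 at 111, 0.146 and 2.24 CPM. Both lead clusters 2 and 3 of the 0 library, and Dcn and Lum lead cluster 22 of the 12.5 library. Dcn and Lum are also among the fixed fibroblast markers. Thbd, H2-Q4, Car9, Ecrg4, Ccdc80, Nr4a2, Mpp7 and Col8a1 were lower, with Car9, which hypoxia induces, at 64.2, 29.7 and 14.0 CPM.

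Tumour genes also differed by chromosome. In the tumour clusters without the low-UMI cluster 5, genes on chromosome 2 had median log2 ratios of −0.36 at 12.5 and −0.30 at 25, and those on chromosome 3 −0.23 and −0.19. Genes on chromosome 11 stood at 0.31 and 0.32, on chromosome 5 at 0.20 and 0.32, and on chromosome 15 at 0.23 and 0.33. Phagocyte-like cells of the same libraries had 0.01 and 0.04 on chromosome 2 and 0.04 and 0.08 on chromosome 11. On chromosome 8, windows from 79028437 to 94660275 stood at −0.74 and −0.74 at 12.5 and at −0.50 and −0.59 at 25, and the window from 116888685 at 0.10 and 0.29. Between the treated libraries, 25 against 12.5, chromosome 8 stood at 0.17 and chromosome 4 at −0.16.

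**Figure D3:**
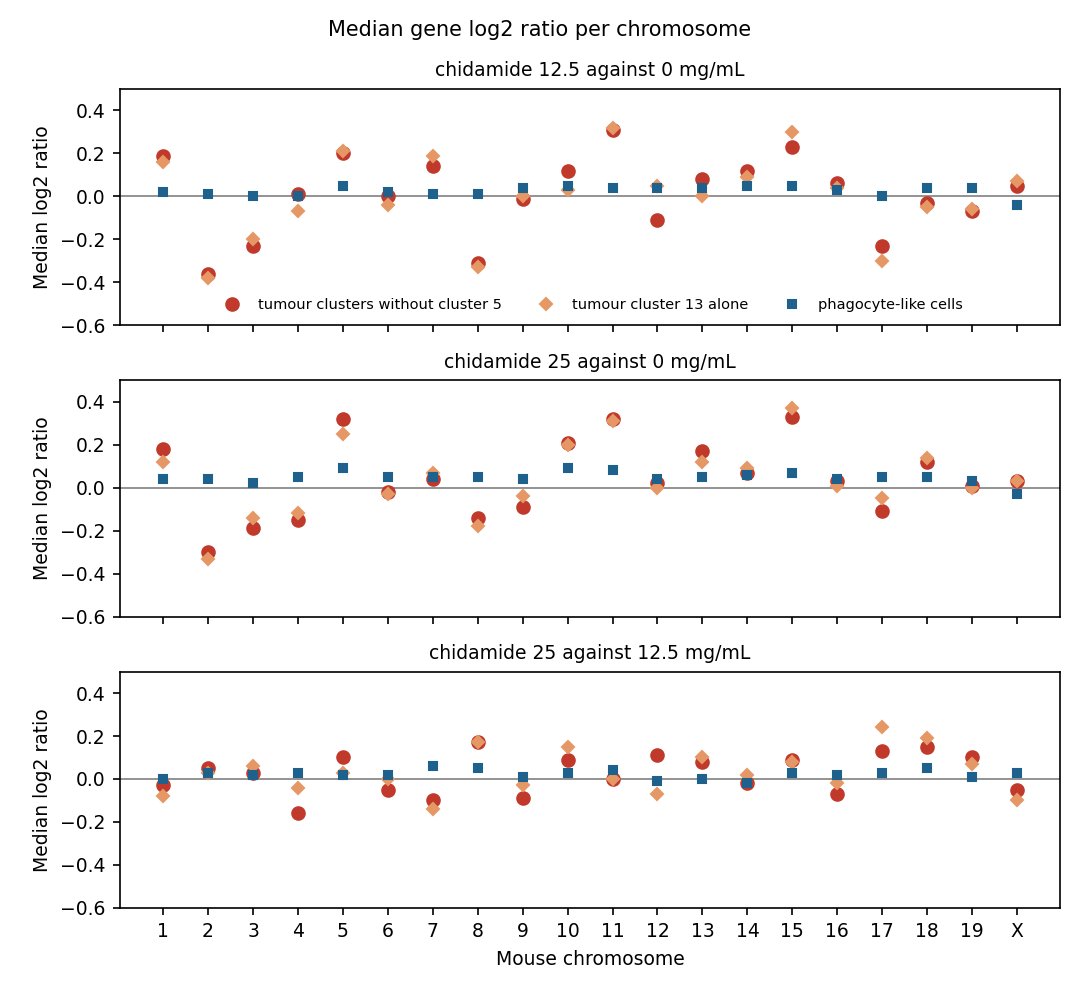
Median log2 ratio of genes (vertical axis) on each mouse chromosome (horizontal axis) for the 3 pairs of libraries, circles for tumour clusters without cluster 5, diamonds for tumour cluster 13 alone and squares for phagocyte-like cells. Tumour clusters stood at −0.36 and −0.30 on chromosome 2 and at 0.31 and 0.32 on chromosome 11 against the 0 library, where phagocyte-like cells stood at 0.01, 0.04, 0.04 and 0.08.

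The score per tumour cell, UMIs on chromosomes 1, 5, 11 and 15 over UMIs on 2 and 3, had medians of 1.15, 1.63 and 1.64. Of tumour cells with at least 10000 UMIs, 144 of 2632 at 0 (5.47% [4.63, 6.41]), 2739 of 2861 at 12.5 (95.7%) and 2881 of 3038 at 25 (94.8%) lay above the midpoint of 1.4. The chromosomes were chosen from differences between these same libraries, and 1.4 lies between the medians of these cells, 1.15, 1.66 and 1.65 by dose. A split between 0 and treated cells was therefore largely set in advance, and these shares only describe it.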

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

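The chromosome slopes of phagocyte-like cells and of cluster 13 were set as tests before their results were seen. Thinning, the stricter filter, separate clustering, doublets kept and the same mix of clusters were fixed before the data were examined, but were taken as tests of an explanation only after their results were seen. The shuffles and the comparison with complement and lipid genes were chosen after the result was seen.

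A pair of unnamed clusters held RNA of more than 1 lineage and hardly any cells of the 0 library, 4 in each. Cluster 20, with tumour genes and neutrophil markers, made up 0.55% of cells at 12.5 and 1.9% at 25. Cluster 21, with tumour genes and phagocyte markers, made up 7.93% at 12.5 and 2.31% at 25, and its median was 6162 UMIs per cell. Shares of all cells count them in the total, no other comparison above used them, and no doublet was called in either treated library.

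Tumour genes differed by chromosome between the 0 library and the treated libraries, and less so between the treated libraries, where the SD of window medians was 2.2 times the highest shuffle and the slope of cluster 13 was 0.76. A technical difference that moves genes by chromosome in every cell type is argued against by the phagocyte-like cells, whose chromosome medians had a slope of at most 0.07 on those of the tumour clusters; neutrophil-like cells, with Krt18 RNA of tumour cells among theirs, had 0.28 and 0.26. An effect that pays no heed to position is argued against in part, since the SD of window medians was at least 2.61 times the highest of 100 shuffles. Shuffling also breaks up neighbouring genes that are expressed alike, so this ratio alone cannot exclude such an effect. Another copy-number state of the tumour cells in the 0 library is a candidate explanation, though no DNA was measured. Within cluster 13, which held cells of every library, the slope was 0.94 or more. That slope argues only against another mix of clusters, because any difference shared by all tumour cells of a library would give it. It cannot tell such a state from an effect on expression in tumour cells that follows position. These data leave open whether such a state was there before treatment or arose or was selected under it. Whether the 0 tumour grew from another line or subline is open too (only the treated titles carry the name pan02). Another line would bear on every comparison with the 0 library. Rhox5 alone cannot decide this, because methylation can silence it and epigenetic drugs can bring it back. Genes nearly absent on 1 side went both ways. Sdc2 had 0, 3274 and 1691 UMIs by dose in the tumour clusters without cluster 5. Tm4sf4 had 7356, 10 and 147 UMIs over all tumour clusters. What made these differences was not tested.

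Neutrophil-like cells made up more, and phagocyte-like cells less, of the immune cells in the treated libraries. Barcodes with few UMIs, kept in unequal numbers, are argued against as the whole cause: with cells thinned to 1000 UMIs the log2 ratio of the neutrophil-like share at 25 was 1.59, though 49.4% of cells at 0 and 12.8% at 25 then stayed unnamed, and with the stricter filter, which also needs 1000 UMIs and left 13.1% and 10.5% unnamed, it was 1.51. With each library clustered alone it was 1.73, so names given by the joint clustering did not make it, and with doublets kept in all libraries it was 1.73 as well. A difference between single tumours that chidamide did not make cannot be told apart from an effect of chidamide, because there was 1 library per group. Digestion and red cell lysis, which the labels describe as fitted to the tissue, stay open in the same way.

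MHC class II genes were lower in the phagocyte-like cells of the treated libraries. Another mix of the phagocyte clusters 0, 1, 7 and 12 is argued against, since with the same mix in every library the medians were −0.90 or lower. The mix of finer sub-clusters was not made the same, so it stays open. Macrophage-like sub-cluster 9 held 413, 39 and 38 cells by dose, and macrophage-like sub-cluster 3 held 62, 143 and 101. Dilution by RNA of other cells is argued against by the complement and lipid genes of the same cells, whose median lay at least 0.32 above that of class II. A difference between single tumours that chidamide did not make cannot be told apart from an effect of chidamide, with 1 library per group. A response of phagocytes to chidamide therefore remains untested.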

How the results depend on the processing

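Chosen after seeing the data were the clustering without list and leading genes, cluster 13 alone, ratios less neighbouring genes, lists without genes over 10 times higher elsewhere, tumour clusters without cluster 5, the top 6% of Scrublet scores and phagocyte sub-clusters at resolution 2.0. The results for shares kept their direction under all 94 alternative values; 74 stayed within the main interval and 20 moved beyond it. Of 800 values of named genes 117 moved and 0 reversed, but 2, those of Arg1 in T cell-like cells at 12.5, turned sign where the main interval reached 0. Of 1084 values of list medians, 176 moved and 30 reversed, which means that the sign turned where the main interval lay on one side of 0; in 41 others the sign turned where that interval reached 0. For all that follows the cause was not tested. After thinning, 49.4% of the 0 library's cells stayed unnamed, against 19.9% and 12.8%. No paired analysis was possible because each group had 1 library.

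For shares, the log2 ratios that moved at 12.5 and 25 were these. With the stricter filter, the phagocyte-like share was −0.42 and −0.58, and the neutrophil-like share at 25 was 1.51. With marker scores per cell, phagocyte-like was −1.11 and −1.65, neutrophil-like 1.03 and 1.24, T cell-like −0.93 and −2.10, and fibroblast-like 5.43 and 3.35. After thinning, phagocyte-like was −0.82 at 25, T cell-like −0.22 and −1.26, and fibroblast-like 1.55 and 1.53. With each library clustered alone, phagocyte-like was −1.29 and fibroblast-like 3.59 at 25. Without list and leading genes in the clustering, fibroblast-like was 1.54 and 1.46.

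Of the list medians discussed first, naive and memory T at 25 was 0.35 with doublets kept, and neutrophil type I interferon at 25 was −0.92 with the stricter filter. Phagocyte MHC class II at 12.5 was −0.44 with doublets kept and −1.0 with the same mix of clusters. Tumour interferon gamma at 12.5 was 0.43 with the mean of cell CPM, 0.16 with the same mix, 0.39 less neighbouring genes and 0.04 in cluster 13; at 25 it was −0.38, −0.38 and −0.76 with the last 3 of these.

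Reversed medians were mostly those of the tumour clusters, where the same mix kept clusters 5, 9, 13 and 16 only. With the same mix of clusters they were, at 12.5, −0.24 for HDAC inhibitor response, −0.63 for type I interferon, −0.30 for naive and memory T, 0.32 for proliferation, −0.39 for pro-inflammatory macrophage and −0.13 for hypoxia. At 25 they were −0.21 for naive and memory T, 0.33 for proliferation and −0.04 for pro-inflammatory macrophage, which the mean of cell CPM gave as −0.30 at 12.5 and −0.11 at 25. Less neighbouring genes, MHC class I was 0.08 and MHC class II 0.14 at 12.5, and HDAC inhibitor response 0.27 at 25. In cluster 13, MHC class II was 0.53 and 0.15, type I interferon −1.15, complement and lipid 0.05 and hypoxia −0.23 at 12.5, and HDAC inhibitor response 0.35 at 25. Without genes over 10 times higher elsewhere, complement and lipid was 0.33 and 0.15.

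In phagocyte-like cells, proliferation was −0.35 at both doses and naive and memory T −0.02 at 12.5 with the same mix, and proliferation was −0.04 at 12.5 with the mean of cell CPM. In T cell-like cells with doublets kept, the regulatory T programme was −0.04 and myeloid-attracting factors 0.02 at 25; alternative macrophage was 0.47 at 12.5 with the stricter filter. In neutrophil-like cells, inhibitory receptors were −0.26 at 25 with no UMI minimum.

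The log2 ratio of the CD8 T-like share, −0.91 and −1.18, was between −0.74 and −0.61 at 12.5 and between −1.48 and −0.69 at 25 under its alternatives. The smallest changes, −0.61 and −0.69, were those of cells with a Cd8a or Cd8b1 UMI, 7 of 54 cells at 25. The T cell-like class had 69 cells at 25.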

Other observations

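Further fixed lists gave these medians. The histone deacetylase genes had tumour medians of −0.05 at 12.5 and 0.02 at 25, and phagocyte medians of −0.01 and 0.09; in tumour cluster 13 alone the median at 25 was 0.46, and in T cell-like cells it was 0.29 [−0.45, 0.65] and 0.40 [−0.61, 0.91]. Apoptosis regulators stood at −0.01 and 0.03 in the tumour clusters and at 0.04 and 0.04 in neutrophil-like cells. Targets of p53, the tumour suppressor, had tumour medians of 0.35 and 0.11, percentiles 99.7 and 71.6 of random lists. Checkpoint ligands, which damp T cells, stood at 0.27 and 0.16 in the tumour clusters and at 0.17 and 0.12 in phagocyte-like cells.

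The list of T-cell-attracting chemokines had medians of −0.17 at 12.5 and −0.30 at 25 in phagocyte-like cells, percentiles 5.1 and 0.1 of random lists, and of −0.27 [−0.85, 0.08] and −0.84 [−1.29, −0.33] in neutrophil-like cells, percentiles 5.5 and 0. In macrophage-like sub-clusters alone the medians were −0.01 and −0.16. Mature dendritic-like cells, which carry antigen to lymph nodes and express Ccr7 and Fscn1, numbered 14, 10 and 7. A sub-cluster of 22 phagocyte-like cells led by Ebf1, Cd79a and Bank1, genes of B cells, could not be named and held 12 cells of the 0 library. No test of a further hypothesis was run.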
